A study of Homo sapiens with 8 samples.

How the data were processed

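Total RNA of HUVEC 36 h after transfection with 20 nM siRNA in a lipid reagent was labelled with Cy3 and hybridised to Agilent one-colour arrays, per the labels' protocols. The 8 samples fall into 4 groups of 2, control, Sox7 knockdown, Sox17 knockdown and double knockdown, taken with their replicate numbers from the sample titles and characteristics. The deposited scanner output holds one array each and gives each spot's brightness as an intensity on a linear scale, extracted with Feature Extraction 11.5.1.1, per the file headers, which name hg19 for the array design. The processed intensity used here was background-corrected by that program, per the file headers. A deposited table of the whole series gives 1 value per probe with its scale, centring and direction unstated. It equalled the mean processed signal of the probe's spots within 0.1% for 99.2% to 99.6% of probes, so that it is on a linear scale and not scaled between arrays. Its column medians lay between 101 and 150, and it served only as an alternative.

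Of the 43118 spots per array that are not controls, 329 to 522 per array carried an outlier flag and were left out; no spot was saturated. The log2 processed signal of a probe's spots was averaged and the array's 75th percentile subtracted (1642 to 2583 in signal units). The remaining 34127 probes were named by their accession without version through a RefSeq gene table of assembly GRCh38.p14, used for names only. One symbol was found for 25771 probes, several for 0 and none for 8356, which stayed out of the main test. Genes that reveal a donor's sex were left out. Where a gene had several probes (4980 genes), the probe with the highest mean over all arrays stood for it. Other probes well above background had a median change of the same sign in 6 of 6 called genes after SOX7 knockdown, 46 of 52 after SOX17 knockdown and 66 of 70 in the double knockdown. Only the sign was compared, so a probe that hardly moved can count as the same. After SOX17 knockdown, for example, GCH1 changed by -0.76 and its other probe by -0.02. No gene named below was among those of opposite sign. Genes were tested if a probe was well above background on both arrays of at least 1 group, which left 13376 of the 19631 genes with complete values; 93 probes lacked a value on some array. No coordinates are given, since the array design and the gene table use different builds.

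Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05) with all 8 arrays, a mean per group and no block. The 4 groups shared one estimate of the spread because each has 2 arrays. An exact permutation test of 2 against 2 arrays cannot go below 0.333. The planned fit with the replicate number as a block is also the fit with the slide as a block, because the file headers place replicate 1 of every group on slide 1 and scan 1 and replicate 2 on slide 2 and scan 2. Deviations of same-numbered arrays from their group means correlated at 0.568 to 0.749 over the 6 pairs of groups. The typical residual SD was 0.174 without the block (4 residual degrees of freedom) and 0.0963 with it (3). Control lay at position 1 of both slides, so position and control cannot be told apart; the other groups changed position.

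A probe well above background on no array of a group has only a bound there. The change is then given as "at least N-fold", from the bright group's mean and, per array of the dim group, the higher of the probe's own level and the lowest level among probes well above background. The 27 gene lists were fixed before the data were examined, from textbook knowledge. The 26 with at least 3 measured members were tested by camera with a preset correlation of 0.01, adjusted over 78 tests of 3 comparisons. The SoxF family had 2 measured members and was not tested as a list. With an estimated correlation, camera uses only the residual degrees of freedom, 4 without the block and 3 with it. That leaves little power over 78 tests, so a list that fails there need not have correlated genes. The rule for named genes, also fixed before the data were examined, took SOX7, SOX17 and SOX18; in each comparison with control, the 8 largest rises and 8 largest falls among genes past the threshold whose knockdown arrays both lay beyond both control arrays, that were well above background on both arrays of a group and that have a gene symbol other than a clone or reading frame; 4 and 4 in the other comparisons; and up to 4 members with the smallest p per described list. Where none passed, it took the 4 smallest p-values. One gene that the rule took is not reported here.

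The alternatives were the block, normexp background correction (offset 50), quantile normalization, the series table, no filter or a filter on all 8 arrays, the mean over a gene's probes, only the groups compared, trend and robust moderation, a change of at least 1, a threshold of 0.01, an estimated camera correlation, fry, and leaving out each array in turn. Normexp was planned on mean spot signals; the files used here give medians, which took their place. Added after seeing the data were each alternative together with the block, probes without a symbol as features, the lists in the direct comparison of the single knockdowns, a test between the slides, the covariance of the single knockdowns across slides, and lists without shared members. The scripts were tested on simulated data: 20 draws of the double knockdown against control over 13376 genes, 200 of them changed. Without the block, 0%, 18.0% and 71.8% of changes of 0.5, 1 and 2 (log2) were recovered with 0.4% false calls. With the block, 21.9%, 85.7% and 98.3% were recovered with 6.8% false calls, more than the adjusted p threshold aims at. Simulated arrays follow an assumed model of the noise, so these rates do not show which fit suits the real arrays. A list of 20 genes shifted by -0.4 was called in 20 of 20 draws and random lists in 0. The noise was drawn independently for each gene. These counts therefore do not show how often lists of correlated genes, such as the interferon list (estimated correlation 0.946), are falsely called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.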

Results

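RNA was measured in human umbilical vein endothelial cells (HUVEC), primary cells that line the vein of the umbilical cord, 36 h after transfection with siRNA at 20 nM. The 4 groups received a control siRNA, an siRNA against SOX7, an siRNA against SOX17, or both. SOX7, SOX17 and SOX18 form the SoxF family of transcription factors, which act in endothelial development. Each group had 2 arrays, taken from 2 independent experiments per the series' design text, and the design asks which genes depend on each factor and whether losing both goes beyond losing one. Nothing in the labels says whether separate donors were used, so p-values measure the spread between these samples. Between 56.7% and 62.0% of the probes on each of the 8 one-colour Agilent arrays were well above background, and the number of arrays limits the precision. Replicate 1 of every group lay on slide 1 and replicate 2 on slide 2. Slide accounted for the first principal component, with 48.4% of the variance over 13376 tested genes. Arrays of different groups on one slide correlated at 0.988 to 0.996 across genes, and arrays of one group on different slides at 0.981 to 0.988.

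Levels below are log2 signal relative to the array's 75th percentile, and changes are log2 differences of group means with the standard error (SE) of the slide-blocked fit. The fit without the slide as a block, which was fixed as the main test, called 0 genes in every comparison at an adjusted p of 0.05 (limma). "Rose", "fell" and "changed" are therefore used here only of genes that passed in the limma fit with the slide as a block, which is the same fit as one with the replicate number as a block. The genes named were chosen by the fixed rule applied to that second fit, a step taken after the main test had called none. Both fits give the same changes and differ only in their errors. The fit without the block leaves out the pairing by slide and counts the difference between the slides as error. Its typical residual SD was 0.174, against 0.0963 with the block, so its 0 calls do not show that no gene changed. No test is possible within a slide, where each group has 1 array, so changes on each slide are given instead.

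The targeted genes were lower where their siRNA was used. SOX7 stood at -1.03 ± 0.43 in control (SD, n = 2) and at -2.70 ± 0.46 in the Sox7 knockdown, which is 31.5% of control. Its change of -1.67 ± 0.20 (SE) was -1.69 on slide 1 and -1.65 on slide 2, and it missed the threshold (adjusted p 0.0611 blocked, 0.646 without the block). In the double knockdown SOX7 stood at 47.7% of control, with a change of -1.07 ± 0.20 (blocked adjusted p 0.0677). SOX17, at 3.26 ± 0.47 in control, fell by 2.01 ± 0.14 in the Sox17 knockdown (24.7% of control, blocked adjusted p 0.0135, 0.205 without the block) and fell by 1.76 ± 0.14 in the double knockdown (29.6% of control, blocked adjusted p 0.0164, 0.236 without the block). Neither factor passed the test after knockdown of the other: SOX7 differed by 0.41 ± 0.20 in the Sox17 knockdown, and SOX17 by 0.12 ± 0.14 in the Sox7 knockdown. SOX18 was well above background on 1 of the 2 arrays of each group and was not tested. Its mean differed from control by -0.04 in the Sox7 knockdown, 0.04 in the Sox17 knockdown and 0.41 in the double knockdown. On slide 1 and slide 2 these differences were 0.16 and -0.24, -0.08 and 0.15, and 0.36 and 0.45. No slide 1 array was well above background for SOX18. The SDs, between 0.81 and 1.26 in the groups, include the difference between the slides.

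**Figure D1:**
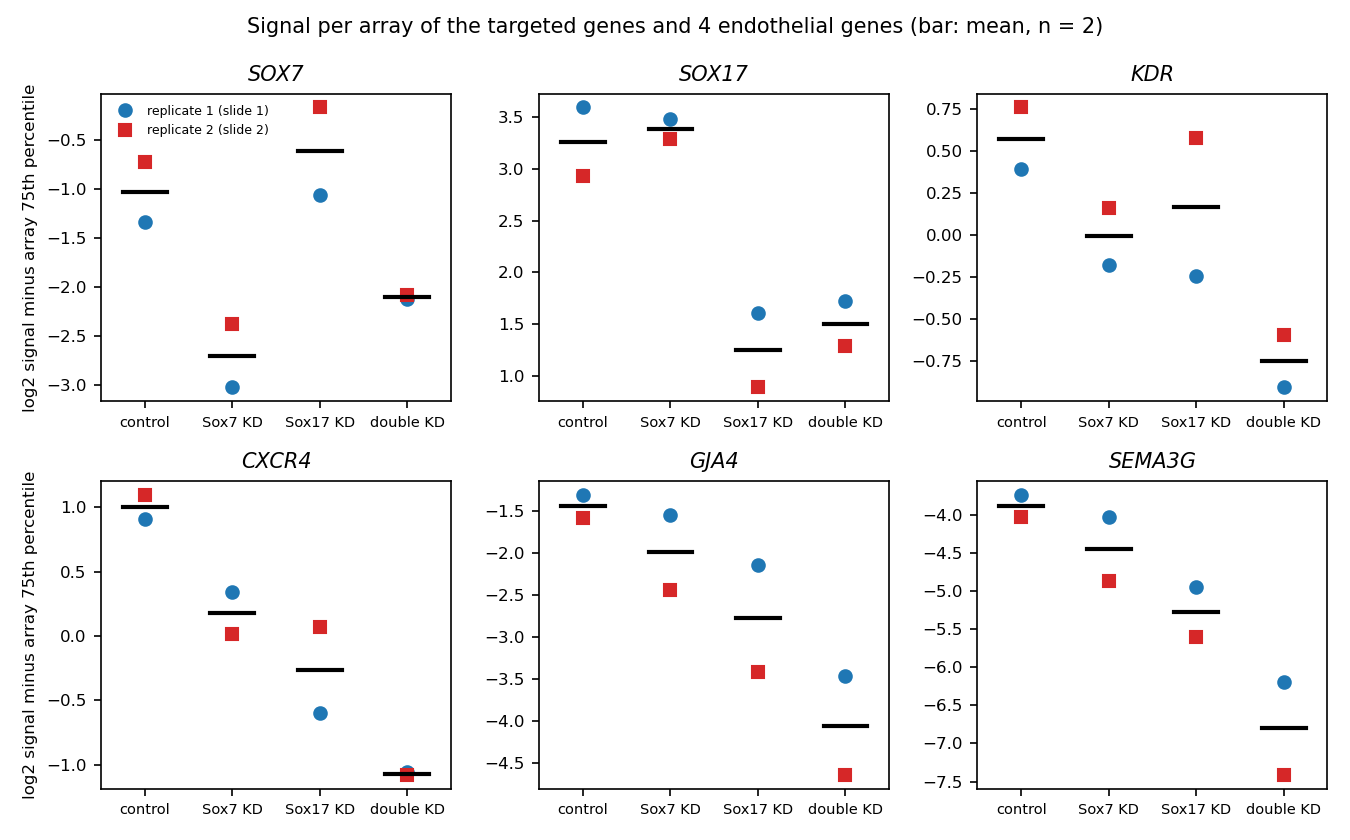
Log2 signal minus the array's 75th percentile (y axis, a different range in each panel) for 6 genes in the 4 groups (x axis); blue circles are replicate 1 on slide 1, red squares replicate 2 on slide 2, and bars the mean of 2 arrays. SOX7 was lower on all 4 arrays that received its siRNA, SOX17 on all 4 that received its own, and KDR, CXCR4, GJA4 and SEMA3G were lowest in the double knockdown.

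After SOX7 knockdown, 25 genes rose and 8 fell in the slide-blocked fit. The largest rise was that of ERLIN2, a protein of endoplasmic reticulum membranes that takes part in protein degradation, with 2.09 ± 0.12 (4.27-fold, 2.22 on slide 1 and 1.97 on slide 2), although a second ERLIN2 probe changed by only 0.55 on average over the 3 knockdowns. The deubiquitinase ATXN3 rose by 1.53 ± 0.06, the interferon-gamma receptor subunit IFNGR1 by 1.32 ± 0.07, the Golgi traffic GTPase ARF4 by 1.21 ± 0.10 and the cell cycle transcription factor E2F5 by 1.17 ± 0.10. FSD1L, ATP2A3, which encodes a calcium pump, and the neurofilament gene NEFM were not well above background on either control array and rose at least 2.55-fold, 1.97-fold and 2.41-fold. Among the falls, the isocitrate dehydrogenase IDH1 fell by 0.96 ± 0.08, IGIP by 1.21 ± 0.10, NAP1L2 by 1.15 ± 0.08, PURA by 0.88 ± 0.08 and SKAP1 by 0.87 ± 0.08. FTLP10 fell at least 2.34-fold to below background, and since it is a pseudogene of the ferritin light chain its probe could also take up copies of the parent gene. Blocked adjusted p-values of these genes lay between 0.0181 and 0.0452. The other 2 falls did not meet the rule for named genes. Of the calls, 14 rises and 4 falls were at least 1 on the log2 scale.

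Without the block, 0 of the 13376 genes passed in this comparison (limma), 697 had an unadjusted p under 0.05, and the smallest p-values, none passing, were those of ATXN3 (adjusted p 0.0643), IFNGR1 (0.158), ERLIN2 (0.186) and ARF4 (0.186). The 33 blocked calls became 0 without either control array, without either double knockdown array, with no filter on dim probes or with only the groups compared, 1 without either Sox17 knockdown array, 2 without Sox7 knockdown replicate 2 and 270 without Sox7 knockdown replicate 1. Changes on the slides correlated at 0.253 across genes, which are not independent replicates.

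By group, the inflammatory activation genes stood above control after SOX7 knockdown. All 11 measured members were higher, with a median of 0.55 (0.69 on slide 1 and 0.57 on slide 2); 0 passed among all genes and 6 in the blocked fit adjusted over the list alone (3 without the block). The chemokines CCL20 and CXCL8 differed by 1.25 ± 0.25 and 0.94 ± 0.21, the cytokine IL6 by 0.54 ± 0.10 and the NF-kappaB inhibitor NFKBIA by 0.44 ± 0.09. The list passed camera's competitive test with a preset correlation (adjusted p 1.42e-05, 0.000396 with the block), and not otherwise: adjusted p = 0.615 with an estimated correlation. Of the 15 BMP and TGF-beta targets, 1 rose, the ligand BMP4 (0.93 ± 0.09), and 4 passed in the blocked fit adjusted over the list alone (2 without the block). TGFB2 at 1.61 ± 0.26, the inhibitory SMAD7 at 0.89 ± 0.16 and BMP2 at 0.86 ± 0.17 did not pass among all genes. That list's median was 0.18 (0.10 and 0.48 on the slides; camera adjusted p 0.0116, 0.0217 with the block; adjusted p = 0.615 with an estimated correlation), and the call was lost without control replicate 2 (adjusted p 0.201) or Sox7 knockdown replicate 2 (0.152).

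The 16 p53 targets had a median of 0.26 (0.10 and 0.43 on the slides; camera adjusted p 0.0481, 0.0663 with the block; adjusted p = 0.615 with an estimated correlation), a call also lost without control replicate 2 (adjusted p 0.427), Sox7 knockdown replicate 1 (0.206) or Sox7 knockdown replicate 2 (0.131), with normexp (0.175), with probes without a symbol kept (0.0553) and without members shared with another called list (0.0865). None passed among all genes and 1 in the blocked fit adjusted over the list alone (0 without the block). The cell cycle inhibitor CDKN1A differed by 0.70 ± 0.08, BBC3 by 0.48 ± 0.15, FDXR by 0.47 ± 0.13 and GDF15 by 0.47 ± 0.11. Tip cell markers, genes of the leading cells of vessel sprouts, had a median of -0.07 over 17 genes (-0.14 and -0.05 on the slides). Their camera adjusted p was 0.0383 (0.144 with the block; adjusted p = 0.562 with an estimated correlation). The call was also lost without control replicate 1 (0.0509), control replicate 2 (0.136) or Sox7 knockdown replicate 1 (0.37), and without members shared with another called list (0.256). None passed among all genes, and 1 passed in the blocked fit adjusted over the list alone (0 without the block). CXCR4 differed by -0.82 ± 0.23, APLN by -0.66 ± 0.22, KDR by -0.58 ± 0.14 and ADM by -0.53 ± 0.09.

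After SOX17 knockdown, 114 genes rose and 92 fell in the slide-blocked fit. BTRC, a ubiquitin ligase subunit that targets beta-catenin, fell by 1.50 ± 0.08, the TNF family ligand TNFSF9 by 1.79 ± 0.10, the mitochondrial fusion gene MIGA1 by 1.94 ± 0.11, the proton pump subunit ATP6V1D by 1.75 ± 0.14, the neuronal growth inhibitor receptor RTN4R by 1.59 ± 0.13 and PREB, which starts vesicle formation at the endoplasmic reticulum, by 1.50 ± 0.07. TMEM178B and FTLP10 fell at least 3.30-fold and 2.58-fold to below background. ERLIN2 rose by 2.16 ± 0.12, CEND1, linked to cell cycle exit of neurons, by 1.97 ± 0.28, CRLF3 by 1.83 ± 0.21 and E2F5 by 1.65 ± 0.10. CIMIP1, CSAG1, the olfactory receptor OR2G6 and the adhesion molecule FLRT3 were below background in control and rose at least 4.38-fold, 1.53-fold, 1.60-fold and 1.47-fold. Their blocked adjusted p-values lay between 0.00826 and 0.0499. Of the calls, 37 rises and 25 falls were at least 1 on the log2 scale.

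Without the block, 0 genes passed (limma), 892 had an unadjusted p under 0.05, and TNFSF9 (adjusted p 0.082), BTRC and ATXN3 (both 0.0836) and ERLIN2 (0.108) had the smallest p-values. The 206 blocked calls became 0 without either control or either double knockdown array, without Sox17 knockdown replicate 1, with no filter on dim probes or with only the groups compared, 1 without Sox17 knockdown replicate 2 and 387 without either Sox7 knockdown array. Changes on the slides correlated at 0.556 across genes.

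Among the lists, tip cell markers were lower after SOX17 knockdown, with a median of -0.23 over 17 genes (-0.23 and -0.11 on the slides). The growth factor gene PDGFB fell by 0.60 ± 0.09. CXCR4 at -1.27 ± 0.23, CD34 at -0.70 ± 0.18 and ADM at -0.43 ± 0.09 did not pass among all genes, while 4 genes passed in the blocked fit adjusted over the list alone (1 without the block). The list's camera adjusted p was 0.0235 (0.0419 with the block; adjusted p = 0.562 with an estimated correlation), and the call was lost without control replicate 2 (0.136) or Sox17 knockdown replicate 1 (0.278), with no filter on dim probes (0.0714) and without members shared with another called list (0.266). Of the 21 interferon response genes, 20 were lower, with a median of -0.61, but -1.08 on slide 1 and -0.24 on slide 2. In the double knockdown, which received the same siRNA, 13 were lower and 8 higher (median -0.17, camera adjusted p 0.723), and in the Sox7 knockdown 19 were higher (0.30, camera adjusted p 0.604). After SOX17 knockdown IFIT3 differed by -0.90 ± 0.18 and XAF1 by -0.95 ± 0.30; no member passed among all genes or adjusted over the list alone, and the list missed the threshold (camera adjusted p 0.132) unless the slide was a block (8.83e-05; adjusted p = 0.779 with the block and an estimated correlation). Single members of other lists rose: the VEGF co-receptor NRP2, which is also a venous marker, by 0.92 ± 0.12 (its 2 other probes by only 0.18 and 0.24), the glucose transporter SLC2A3 by 1.28 ± 0.14 and AGO2, the slicer of RNA interference, by 0.49 ± 0.07.

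In the double knockdown, 189 genes rose and 127 fell in the slide-blocked fit, and the falls included genes of arterial and sprouting endothelium. The vessel guidance gene SEMA3G fell at least 3.26-fold to below background, the gap junction gene GJA4 fell by 2.61 ± 0.25, the chemokine receptor CXCR4 by 2.07 ± 0.23 and KDR, the main signalling receptor for VEGF, by 1.33 ± 0.14. MIGA1 fell by 1.94 ± 0.11, and TMEM178B, the protease gene KLK10, CBLN2 and FTLP10 fell at least 2.50-fold, 1.87-fold, 2.10-fold and 1.95-fold. IL1RL1, an interleukin receptor, rose by 2.41 ± 0.34, ERLIN2 by 1.99 ± 0.12, the transcription factor FOXS1 by 2.08 ± 0.25 and CEND1 by 1.84 ± 0.28. CFAP46, the calcium channel RYR2, MS4A6A and GAL3ST4 were below background in control and rose at least 2.06-fold, 1.53-fold, 2.72-fold and 2.40-fold. Their blocked adjusted p-values lay between 0.0107 and 0.0482. Of the calls, 61 rises and 51 falls were at least 1 on the log2 scale.

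Without the block, 0 genes passed (limma), 911 had an unadjusted p under 0.05, and TNFSF9, ATXN3, IFNGR1 and BTRC had the smallest p-values (adjusted p 0.118 for each). The 316 blocked calls became 0 without either control, either Sox17 knockdown or either double knockdown array, and with no filter on dim probes, 172 with only the groups compared and 581 without either Sox7 knockdown array. Changes on the slides correlated at 0.525 across genes.

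Tip cell markers were lower in the double knockdown in 15 of 17 measured members, with a median of -0.31 (-0.30 and -0.35 on the slides). CXCR4, KDR and the vasodilator peptide gene ADM (fell by 0.92 ± 0.09) passed among all genes, CD34 at -0.90 ± 0.18 did not, and in the blocked fit adjusted over the list alone 8 fell and 1 rose (3 fell without the block). The list's camera adjusted p was 1.42e-05 (0.000202 with the block), against adjusted p = 0.388 with an estimated correlation. Endothelial identity and junction genes had a median of -0.17 (-0.16 on both slides), with falls of KDR, the tight junction gene CLDN5 (fell by 0.90 ± 0.11) and VWF, which encodes von Willebrand factor (fell by 0.99 ± 0.15), and 18 of 25 members below control. Adjusted over the list alone, 6 fell and 1 rose in the blocked fit (0 without the block); camera gave an adjusted p of 0.00767 (0.00266 with the block; adjusted p = 0.562 with an estimated correlation; 0.166 without members shared with another called list). In the same comparison 6 of 7 epithelial markers were above control, and 1 of them passed among all genes: KRT19, at 3.63 in control, rose by 0.53 ± 0.08 (blocked adjusted p 0.0482).

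Arterial markers had a median of -0.12 over 14 genes (-0.19 on both slides) and a mean of -0.51, carried by the 3 that fell: SEMA3G, GJA4 and CXCR4. IGFBP3, in the same list, stood at 1.62 ± 0.49 and did not pass. Adjusted over the list alone, 4 fell in the blocked fit (3 without the block), and camera gave an adjusted p of 0.0116, lost with the block (0.0663), with a filter on all 8 arrays (0.0654) and without members shared with another called list (0.171); it was adjusted p = 0.562 with an estimated correlation. The inflammatory activation genes had a median of 0.51 (0.83 on slide 1, 0.15 on slide 2). IL6 rose by 0.94 ± 0.10, while CCL20 at 1.38 ± 0.25, CXCL8 at 1.16 ± 0.21 and CXCL2 at 0.55 ± 0.15 did not pass; the chemokine CCL2, named for its direction after its value was seen, fell by 1.40. Adjusted over the list alone, 4 rose and 1 fell in the blocked fit (3 rose without the block). Their camera adjusted p was 0.00767, lost with the block (0.138), with no filter on dim probes (0.085) and without double knockdown replicate 1 (0.266); it was adjusted p = 0.615 with an estimated correlation.

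**Figure D2:**
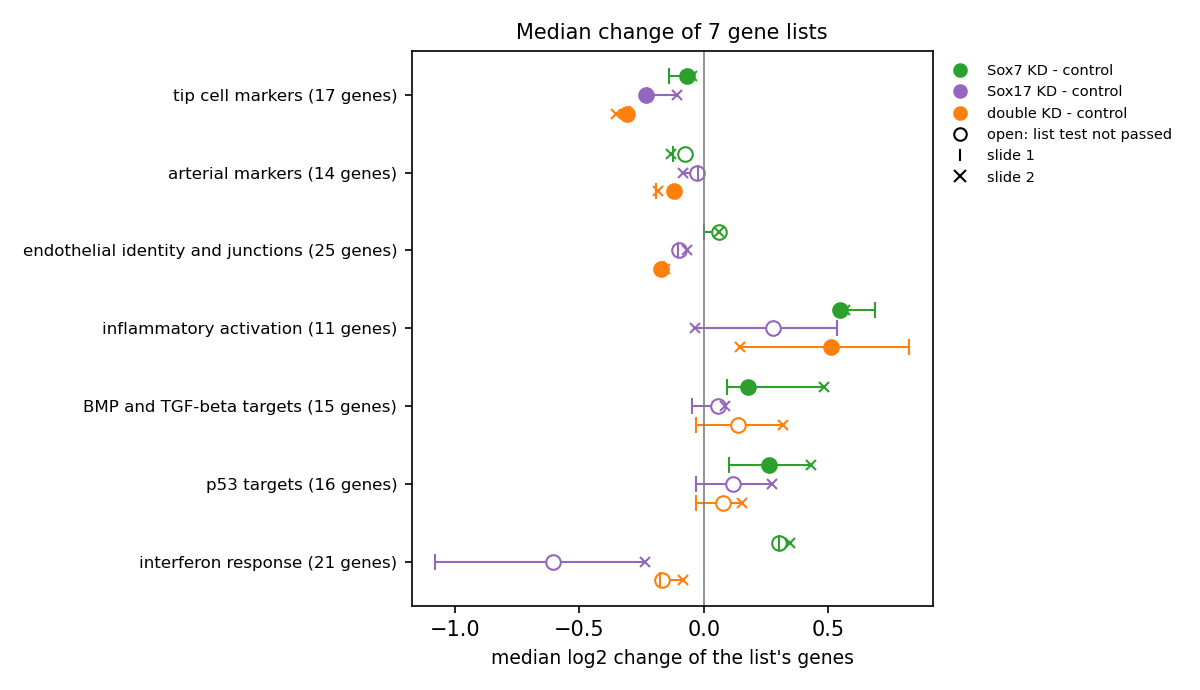
Median log2 change (x axis) of the genes of 7 lists (y axis, with the number of genes) in each knockdown against control; circles are medians of the change over both slides, filled where camera with the preset correlation passed, and ticks and crosses are medians on slide 1 and slide 2. The tip cell list lay below 0 in all 3 knockdowns, at -0.31 in the double knockdown, and the interferon list at -0.61 after SOX17 knockdown. No filled list passed with an estimated correlation, where camera has only 4 residual degrees of freedom.

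The remaining lists passed camera in none of the 3 comparisons with control, with medians given here for the Sox7, Sox17 and double knockdown in that order. Venous markers had medians of 0.30, 0.16 and 0.28, and the 3 measured lymphatic markers 0.22, 0.38 and 0.76. VEGF ligands and receptors lay at -0.01, 0.03 and 0.00, VEGF-induced genes at 0.00, -0.13 and -0.14, and Notch ligands, receptors and targets at -0.06, 0.12 and -0.07. JAG2, a Notch ligand, fell by 0.52 ± 0.07 in the double knockdown. Adhesion and permeability regulators lay at 0.07, 0.07 and -0.06, with a rise of the sphingosine phosphate receptor S1PR3 by 0.97 ± 0.11 in the double knockdown. Proliferation genes had medians near 0: those of the S phase list were -0.04, 0.06 and 0.06, and G2/M medians 0.00, 0.07 and 0.08. Unfolded protein response and ATF4 targets had medians of -0.06, 0.09 and 0.01, cholesterol synthesis 0.04, 0.07 and 0.09, hypoxia and glycolysis 0.01, -0.01 and 0.04, and Wnt/beta-catenin targets -0.01, 0.17 and 0.17. Basement membrane and matrix genes lay at 0.14, -0.10 and -0.04 and mesenchymal transition genes at 0.13, 0.01 and 0.00. Markers of other cell types did not pass as lists either: fibroblast and smooth muscle medians were 0.18, -0.35 and -0.40, leukocyte -0.08, 0.15 and 0.13, epithelial 0.10, 0.09 and 0.34, and erythroid 0.04, -0.02 and 0.01. RNA interference genes had medians of 0.02, 0.17 and 0.08. Of their 225 list members, a gene in several lists counting in each, 0, 4 and 8 passed among all genes in the blocked fit and 24, 17 and 34 adjusted over the list alone; without the block 0 passed among all genes, and 5, 5 and 7 adjusted over the list alone. The smallest camera adjusted p among these 19 lists was 0.144. Median, mean and test differed in sign in 16 of the 78 list tests, none of them passing. With the block, the matrix list passed after SOX7 knockdown (adjusted p 0.00834; 0.14 and 0.20 on the slides; adjusted p = 0.779 with the block and an estimated correlation).

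The single knockdowns differed from each other directly. Against the Sox7 knockdown, 37 genes were higher and 73 lower in the Sox17 knockdown in the slide-blocked fit, with 0 passing and 870 at an unadjusted p under 0.05 without the block (limma). The targets themselves parted, SOX7 by 2.08 ± 0.20 and SOX17 by -2.14 ± 0.14. LUM, which encodes the matrix proteoglycan lumican, was at least 4.58-fold lower in the Sox17 knockdown, where it was not well above background, PLA2G2D, well above background on 1 of the 2 Sox17 knockdown arrays, differed by -4.02 ± 0.49 and RTN4R by -2.15 ± 0.13. CIMIP1 was at least 4.54-fold higher, SERPIND1, a thrombin inhibitor, differed by 1.39 ± 0.07 and TENT5C by 1.38 ± 0.17. BTRC, MECR, SLC25A15 and AKAP8L had the smallest p-values without the block (adjusted p 0.305 each). The 110 calls became 0 without either control, either Sox17 knockdown or either double knockdown array, with no filter or with only the groups compared, 2 without Sox7 knockdown replicate 2 and 796 without Sox7 knockdown replicate 1.

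Set against the single knockdowns, the double knockdown differed from the Sox7 knockdown in 24 genes, 3 higher and 21 lower, and from the Sox17 knockdown in 0. RSPH9 was higher than in the Sox7 knockdown by 1.06 ± 0.09, while SOX17 differed by -1.88 ± 0.14, RTN4R by -1.90 ± 0.13, and LUM and SEMA3G were at least 3.47-fold and 2.20-fold lower. SOX7 differed by 0.60 ± 0.20 (blocked adjusted p 0.292) from its level in the Sox7 knockdown. Without the block, 0 genes passed and 567 had an unadjusted p under 0.05 (limma), the smallest p-values being those of BTRC, SLC25A15, MECR and BRI3 (adjusted p 0.617 each). The 24 calls became 0 without either control, either Sox17 knockdown or either double knockdown array, with no filter or with only the groups compared, 2 without Sox7 knockdown replicate 2 and 177 without Sox7 knockdown replicate 1. Against the Sox17 knockdown, 118 genes had an unadjusted p under 0.05 without the block and 556 with it (limma). The genes with the smallest p-values there, none passing, were RYR2, CFAP46, CELA3B and PCDHB8 (adjusted p 0.878 for the first 3 and 1 for PCDHB8). SOX7 differed by -1.48 ± 0.20 and SOX17 by 0.26 ± 0.14.

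No gene passed the interaction test, which asks for a departure from the sum of the single knockdowns. An unadjusted p under 0.05 was reached by 213 genes without the block and 951 with it (limma, smallest adjusted p 0.511 and 0.0587). A missed threshold does not show that the changes add. The sum also assumes that each target is lowered equally in the single and double knockdown. SOX7 stood at 31.5% of control in the Sox7 knockdown and at 47.7% in the double knockdown, a difference that did not pass. The smallest p-values were those of ATXN3, FTLP10, ERLIN2 and IFNGR1. The interactions of ATXN3, ERLIN2 and IFNGR1, at -1.53 ± 0.09, -2.26 ± 0.17 and -1.25 ± 0.10, were opposite in sign to their changes in each knockdown. A gene with the same change in all 3 knockdowns has an interaction of minus that change. These 3 genes changed nearly alike in each, so the sign does not show that the knockdowns oppose each other. Control arrays standing apart, weighed below, would also give it. FTLP10 was not well above background in any knockdown, so its interaction has no usable value. The interaction was 0.19 ± 0.29 for SOX7 and 0.13 ± 0.20 for SOX17.

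Genes called in both single knockdowns numbered 21 in the slide-blocked fit, 18 that rose and 3 that fell, and 0 without the block. ERLIN2, ATXN3, IFNGR1, ARF4, E2F5, ATP2A3 and NEFM were among the rises, and FTLP10, NAP1L2 and SKAP1 were the falls. In 100 simulations of unchanged groups against the shared controls, the shared calls averaged 0.01 and reached 1. Hardly any gene is called when no group changes, so a count near 0 was fixed by that setting. It does not show how much overlap the shared controls add to the lists called here. The 21 became 0 without either control or either double knockdown array, without Sox7 knockdown replicate 2, without Sox17 knockdown replicate 1, with no filter or with only the groups compared, 1 without Sox17 knockdown replicate 2 and 55 without Sox7 knockdown replicate 1. Independent lists of these sizes would share 0.21 rises and 0.06 falls. The Sox17 and double knockdown shared 156 calls and the Sox7 and double knockdown 24, with none in opposite directions. Across genes, the changes of the single knockdowns had a covariance of 0.0419 against 0.0133 in the simulation, a difference of 0.0285, and a correlation of 0.438 against 0.5. With the Sox7 change taken from one slide and the Sox17 change from the other, which share no control array, the covariance was 0.0297 and 0.0237 in the 2 pairings.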

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

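The tests of scaling, of off-target action and of the ratio to the double knockdown were chosen after their results had been seen, as was the use of the slide-blocked fit for all counts in this part. The direct test between the single knockdowns called 110 genes, and 66 of them lay on opposite sides of control in the 2 knockdowns on both slides. Of the 66, 60 were well above background in control and both single knockdowns. Choosing genes by this difference on the same arrays favours opposite sides of control. The 66 include SOX7 itself and genes close to control on one side, such as STARD7 (0.01) and BRI3 (0.05) after SOX7 knockdown. No gene was called against control in opposite directions in the 2 single knockdowns. SERPIND1 (-1.10 after SOX7 and 0.29 after SOX17 knockdown) differed by 1.39 between them, and of these 2 changes from control that after SOX7 knockdown passed the test (blocked adjusted p 0.026). Probes without a gene symbol, which no comparison used, gave 2 calls after SOX7 knockdown, 14 after SOX17 knockdown and 21 in the double knockdown among 3095 tested. One of them, singled out after its values were seen, was the only feature called without the block when these probes were kept: A_33_P3343200 was not well above background in any knockdown and at least 3.86-fold, 4.25-fold and 3.21-fold lower than in control in the Sox7, Sox17 and double knockdown (limma adjusted p 0.0255, 0.021 and 0.0399).

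A first pattern is the 21 genes changed alike in both single knockdowns, all 21 of which were also called in the double knockdown; leaving out 1 array gave 0 to 55 such genes. Simulated unchanged groups with shared controls reached at most 26 genes with an unadjusted p under 0.01 in all 3 comparisons. The observed number was 276, more than noise drawn independently for each gene and array gave. Deviations common to many genes of a control array were not simulated, and no simulated group changed. Chance in the control arrays therefore stays open. The median ratio of the double knockdown change to the mean single change was 0.99 (0.65 to 1.76), near the value of 1 that is needed if the control arrays stand apart through their siRNA, their culture or their position on the slide, and far from a sum of effects. A sum also assumes that SOX7 is lowered equally in the single and double knockdown, where it stood at 31.5% and 47.7% of control. A response to either siRNA that is already full in the single knockdowns would give the same ratio and stays open. A faulty probe also stays open, since only 3 of the genes had another usable probe (median 0.79 of the change).

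A second pattern is the 72 genes, SOX17 left out, that were lower under the Sox17 than under the Sox7 siRNA, against 36 higher with SOX7 left out. Scaling between arrays is argued against as the source of these differences, each of which was at least 0.54 in size: with all genes divided by intensity into 10 parts, the median difference was largest in size at -0.031, and on single slides at -0.098. With both targets counted, 66.4% of the 110 calls were lower, and 62.8% of 94 after quantile normalization. Of the 72 genes, 49 stood above control on both slides in the Sox7 knockdown and 68 below control in the Sox17 knockdown, which the choice of these genes on the same arrays favours. In the double knockdown, whose arrays, like those of control, do not enter that difference, 58 of the 72 lay below control on both slides (median -0.51), against 32.1% of all genes. Loss of SOX17 and an off-target action of the same siRNA cannot be told apart by this, because the design has 1 siRNA per target and its sequence was not used here.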

How the results depend on the processing

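The fit without the block called 0 genes in all 7 comparisons under all alternatives run, with these exceptions: the slide or replicate block itself, probes without a symbol kept (1 gene in each comparison with control and 1 shared by the single knockdowns), and a filter on all 8 arrays or trend and robust moderation (1 gene each after SOX7 knockdown). The replicate block moved the calls from 0 to 33, 206 and 316 for the Sox7, Sox17 and double knockdown against control, 110 for Sox17 against Sox7 knockdown, 24 for double against Sox7 knockdown and 21 for the overlap of the single knockdowns; double against Sox17 knockdown and the interaction stayed at 0. All further combinations with the block were chosen after seeing the data.

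With the replicate block, no filter on dim probes gave 0 calls in each comparison, and a threshold of 0.01 gave 0 except 17 after SOX17 knockdown. In the order just given, normexp gave 93, 322, 441, 214, 63 and 38, with 1 call for double against Sox17 knockdown; a filter on all 8 arrays 71, 371, 452, 230, 38 and 36; trend and robust moderation 131, 447, 579, 294, 98 and 65, with 3 for the interaction; the mean over probes 15, 102, 192, 55, 16 and 10; probes without a symbol kept 16, 105, 217, 36, 15 and 11; a change of at least 1 gave 18, 62, 112, 41, 17 and 11; quantile normalization 15, 151, 294, 94, 23 and 10; the deposited series values 21, 170, 260, 99, 25 and 15. With only the groups compared, 0 genes were called except 172 in the double knockdown against control. Leaving out 1 array with the replicate block gave 0 to 270, 0 to 387, 0 to 581, 0 to 796 and 0 to 177 calls in the 5 comparisons, 0 to 2 for the interaction and 0 to 55 for the overlap. A fit without an array has 1 residual degree of freedom fewer and assumes that the lone array varies like the other groups; beyond that and the fewer genes of stricter filters the cause was not tested.

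The 9 list calls became 0 with an estimated correlation, 1 with fry and 4 without members shared with another called list; leaving out 1 array gave 7 to 12, and the replicate block 7, of which 5 were among the 9. No called list turned its direction. The tip cell list in the double knockdown had an estimated correlation of -0.022, below the preset 0.01. Its unadjusted camera p still went from 1.98e-07 to 0.00498, so correlation between its genes does not account for that loss. For the inflammatory list the estimate of 0.262 lay above the preset. Changes that turned sign when 1 array was left out, all of genes that did not pass in that comparison, are given with their range over the left-out arrays. SOX17 after SOX7 knockdown ran from -0.21 to 0.45 (-0.08 without Sox7 knockdown replicate 2, with the replicate block), SOX7 after SOX17 knockdown from -0.03 to 0.86, and SOX17 between the double and Sox17 knockdown from -0.10 to 0.62. KRT19 after SOX7 knockdown ran from -0.12 to 0.58. After SOX17 knockdown, KDR ran from -0.82 to 0.00, XAF1 from -1.97 to 0.07 and IFIT3 from -1.90 to 0.10, the last 2 above 0 without control replicate 1. Interactions ran from -0.23 to 0.49 for SOX17 and from -0.26 to 0.63 for SOX7; with the replicate block they turned to -0.07 and -0.01 for SOX17 and to -0.04 and -0.15 for SOX7. Without the block, leaving out 1 array compares a group on 1 slide with a group on both slides. The difference between the slides then enters the change, so these ranges do not measure the spread of the effect alone. The cause of the turns with the replicate block, which adjusts for the slide, was not tested. Quantile normalization moved the median change of all genes in the 3 comparisons with control from 0.02, 0.01 and 0.02 to -0.01 in each. Genes not well above background in a group, such as SEMA3G in the double knockdown, have only a bound on their change.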

Other observations

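The tests between the slides, the comparison of lists between the single knockdowns and the reading of the test on held-out slides were settled after their results had been seen. Interferon response genes differed more between the 2 slides than between any groups. Their median was 1.85 lower (log2) on slide 2 than on slide 1, with all 21 measured members lower and medians of -2.05 to -1.23 within the 4 groups, against -0.03 over all 13376 genes. Relative to the mean of its slide, the list's mean level stood at -0.88 and -0.25 in the Sox17 knockdown, at 0.54 and 0.29 in the Sox7 knockdown, at 0.25 and -0.03 in control and at 0.09 and -0.01 in the double knockdown. Mesenchymal transition genes (-0.64), inflammatory activation genes (-0.55) and matrix genes (-0.43) were also lower on slide 2. Tested between the slides with the groups in the fit (limma), 3376 genes were lower and 2713 higher on slide 2, among them 20 interferon response genes, all lower. That list passed camera (adjusted p 1.95e-08, 0.95 with an estimated correlation), as did the matrix genes (0.00582, 0.866 with an estimated correlation), while the inflammatory (0.428) and mesenchymal transition genes (0.348) did not. G2/M genes were higher (0.19; 0.00582, 0.95 with an estimated correlation). The cause cannot be named, since slide and experiment have the same arrays.

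In the direct comparison of the single knockdowns, 4 lists passed camera as lower in the Sox17 than in the Sox7 knockdown. Interferon response genes had a median of -0.86 (-1.19 on slide 1 and -0.50 on slide 2; adjusted p 0.0204, 7.02e-08 with the block), with 20 of 21 lower and none called singly. Basement membrane and matrix genes lay at -0.26 (-0.28 and -0.23; adjusted p 0.0204), BMP and TGF-beta targets at -0.23 (-0.15 and -0.41; adjusted p 0.0204) and inflammatory activation genes at -0.47 (-0.25 and -0.60; adjusted p 0.0386). None passed with an estimated correlation, all 4 with adjusted p = 0.745. Fibroblast and smooth muscle markers, LUM among them, lay at -0.63 but at 0.04 on slide 1 and -0.92 on slide 2, and missed the threshold (adjusted p 0.0573, 0.115 with the block). Mesenchymal transition genes lay at -0.28 and passed only with the block (adjusted p 0.181, 0.0211 with the block). Whether the groups differed in their share of other cells was not tested.

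One hypothesis was tested on its own: that the double knockdown lowers genes further than either single knockdown, as KDR, CXCR4, GJA4 and SEMA3G were ordered, rather than appearing so because genes were chosen on the same arrays. Of the 50 genes with the lowest double knockdown change on slide 1, 23 lay below both single knockdowns on slide 2, and in the reverse split 28 of 50 did. On slide 2 the chosen genes had medians of -0.50 in the Sox7, -0.57 in the Sox17 and -1.11 in the double knockdown, against -1.16 for the sum of both, and on slide 1 -0.11, -0.45, -0.48 and -0.53. About 16.7 of 50 are expected if all 3 knockdowns are alike. If the double knockdown equals the single knockdown with the larger fall, at most 25 are expected, and fewer where both single knockdowns are alike. Of all genes, 26.6% on slide 1 and 19.2% on slide 2 lay below both. As 25 is only an upper limit, counts of 23 and 28 do not decide whether the falls go beyond the larger single fall. On slide 1 the double knockdown median was near that of the Sox17 knockdown, so selection stays open as a source of part of the pattern. The sum has the limit given for the interaction test. The medians of these falls lie near the sum of the single changes. The 50 highest genes did not: their double knockdown median was 0.58 against 0.78 for the sum on slide 2, and 1.099 against 1.71 on slide 1. The interaction test called no gene.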
